A study of Mus musculus with 6 samples.

How the data were processed

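RNA from the kidney cortex of 6 male C57BL/6 mice was measured on Illumina MouseWG-6 v2 bead arrays, 1 mouse per array. The 3 captopril mice had taken the drug in drinking water at 10 mg/kg/day for 7 days from 11 weeks of age, and 3 mice were controls, per the labels. Each array was placed in its group by its treatment label and named by the replicate number of its title. The number of arrays, 3 per group, limits the precision of every value.

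The deposited scanner-level table gave a bead-averaged signal intensity on a linear scale for 45281 probes on each array, per the file headers. Medians of that intensity differed between arrays (111 to 147) and the lowest values lay between 77.9 and 102, so the table was neither normalized between arrays nor background-subtracted. The table also gave a detection p-value beside each deposited signal, per the file headers. These p-values moved in steps of 1 over 936, and the software that made them is not given in the sources used here. A second deposited table held the authors' processed values on a log2-like scale, and lumi, with no version, is named as a tool per the submitters' processing notes. The transform and the normalization are not given in the sources used here. Set against the scanner values, each processed column ranked the probes exactly as its own array did, and all columns had the same median of 7.94 and floor of 7.76. The slope of the authors' values on log2 intensity was 0.38 to 0.44 for signals under 150 and 1.01 to 1.08 for signals over 5000. The processed values are therefore compressed at the dim end, run in the same direction as the intensity and are not centred per gene. They were used only as an alternative.

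Background was corrected with limma's neqc, which fits normal and exponential components, takes the negative-control distribution from the detection p-values, adds an offset of 16, normalizes by quantiles and takes log2. Probes with a detection p under 0.05 on at least 3 of the 6 arrays, whichever the group, were tested, which left 16500 probes. Captopril was compared with control by lmFit and eBayes in limma on all 6 arrays, without covariates, two-sided, with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05. All log2 fold changes are captopril minus control, and SE and 95% intervals come from that fit. Exact permutation of 3 against 3 arrays cannot give a p below 0.1, so single genes were tested only through the fit over all probes.

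Probe names came from GEO's annotation of the platform. It listed 34903 of the probes, of which 34885 had 1 gene symbol and 18 had several. The 10396 probes without a single symbol, those 18 included, are unnamed here. Gene identifiers of 34807 probes were found in a mouse gene table and 0 symbols needed an update. Of the tested probes, 14326 had 1 symbol, which gave 9718 genes. A gene with several tested probes was represented by the probe with the highest mean over the 6 arrays, and disagreement between its probes is stated. Ren1 and Akr1b7 had 0 named probes, so the Ren1 response fixed in the design was not analysed here. Positions of probes in the genome were not used here.

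The text names genes by a rule fixed before the data were examined. It took in each direction the 12 genes with the largest change among those past the threshold with no overlap between the groups. Where fewer passed, places went to non-overlapping genes with the smallest unadjusted p and an absolute log2 change of at least 0.5. It also took every tested member of the renin-angiotensin list. From each list past its threshold, and from the circadian clock, immediate early, and juxtaglomerular and macula densa lists, it took members past the threshold or else up to 4 with the smallest unadjusted p. Genes named outside that rule were chosen after their values were seen, as stated there. A gene not detected on any array of 1 group has only a bound. The bright group's mean was then set against the mean of, per array, the higher of the gene's own value and the lowest value among detected probes, and written as at least N-fold. Such a bound holds on the neqc scale only and takes no account of sampling error.

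Before the data were examined, 36 gene lists were fixed for kidney cell types, pathways, other tissues that a dissection could bring in, blood cells and time of day. They held 615 genes, of which 543 had a named probe and 404 were tested. The 32 lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and the rotation test fry were run beside it.

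Alternatives fixed beforehand were no background correction, normexp without negative controls at offset 50, median scaling, the authors' processed values, no filter, detection p under 0.01 on all 6 arrays, and eBayes with trend and robust options. Array weights, the replicate number as a block, leaving out each array, the mean of a gene's probes and other thresholds completed that set. Two-sided correlations over the 6 arrays were tested exactly over all 720 pairings. The fit was tested on simulated data of 16500 probes with 200 changed, over 20 repeats of the comparison of captopril with control. It recovered 5% of probes changed by 0.58 on the log2 scale, 56% at 1, 89.7% at 1.5 and 97.5% at 2.3, and 5.19% of its calls were false. The simulated probes varied independently, and Benjamini-Hochberg adjustment is stricter where fewer probes change. These shares therefore overstate the recovery where few probes change, and changes of such sizes may have been missed here. R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.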

Results

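Gene expression was measured in the kidney cortex of male C57BL/6 mice given captopril, an inhibitor of the angiotensin-converting enzyme, and of control mice, with 3 mice per group and 1 bead array per mouse. The comparison asks which transcripts differ in the cortex after 7 days of inhibition. Between 16372 and 17312 probes per array, or 36.2% to 38.2%, were detected above negative controls. Arrays resembled each other closely, with a correlation across probes of 0.984 to 0.987 for every pair, a mean of 0.985 within groups and 0.986 between groups. Probes are not independent replicates. No pair of arrays held identical values.

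In limma, 3 probes were lower in captopril cortex and 0 were higher past the threshold, against 336 lower and 371 higher at an unadjusted p under 0.05. ILMN_2620114 fell by 2.37 on the log2 scale (SE 0.15), from 12.69 ± 0.07 in control to 10.32 ± 0.21 in captopril cortex (SD, n = 3 per group), with adjusted p = 0.00275 in limma. ILMN_2777226 fell by 2.41 (SE 0.16), from 9.96 ± 0.08 to 7.55 ± 0.28, with adjusted p = 0.00293 in limma. ILMN_1238042 fell by 1.56 (SE 0.16), from 7.91 ± 0.08 to 6.36 ± 0.24, with adjusted p = 0.0397 in limma. In linear terms these probes were 5.18-fold, 5.31-fold and 2.94-fold dimmer, and each captopril array lay below each control array. The size depended on the processing, since ILMN_1238042 stood at -0.82 on the log2 scale without background correction and at -0.51 in the authors' values, and ILMN_2777226 at -1.46 in the authors' values. The annotation used here gives these probes no gene name. The call of ILMN_1238042 was lost in limma without control arrays 1, 2 or 3 (adjusted p = 0.259, 0.173 and 0.200) and without captopril arrays 1, 2 or 3 (0.171, 0.117 and 0.222). It was also lost in limma with median scaling (adjusted p = 0.273), without the detection filter (0.0604) and with a brown fat covariate chosen after seeing the data (0.0905). With the replicate number as a block, 0 of the 3 passed in limma.

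Cdk5rap1, which encodes a mitochondrial tRNA-modifying enzyme, had the largest decrease in value among the named genes below. Its probe ILMN_1249441 stood at 8.67 ± 0.52 in control and 7.15 ± 0.42 in captopril cortex (SD, n = 3), a log2 difference of -1.51 (SE 0.29), and did not pass the threshold (adjusted p = 0.952 in limma). The gene's other probes, ILMN_2602821 and ILMN_2604985, gave -1.27 and -1.68, also with every captopril array below every control. With the trend and robust options of eBayes in limma, ILMN_2602821 passed (adjusted p = 0.0099), whereas ILMN_1249441 did not (adjusted p = 0.995). The difference of ILMN_1249441 was -0.99 without background correction and -0.70 in the authors' values. Among all alternatives its adjusted p ran from 0.0506 to 1.00.

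**Figure D1:**
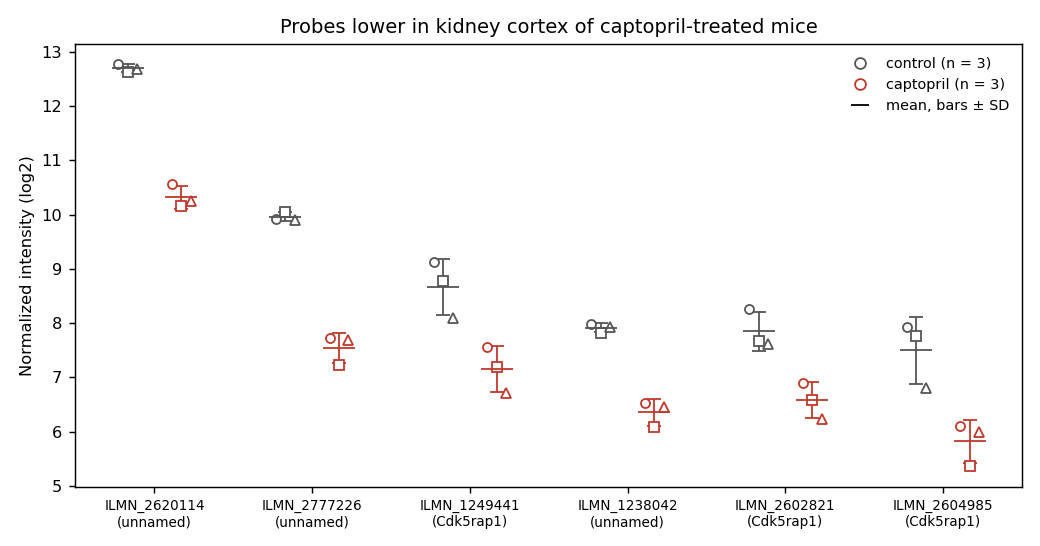
Normalized intensity (log2) of the 3 unnamed probes that passed the threshold and of the 3 Cdk5rap1 probes that did not, on each control (grey) and captopril (red) array; symbols mark the replicate number, horizontal lines the group mean and bars 1 SD (n = 3). Every captopril array lies below every control array for all 6 probes, from a mean of 12.69 against 10.32 for ILMN_2620114 to 7.85 against 6.58 for ILMN_2602821.

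Of the 9718 named genes, 0 passed the threshold in limma, where the smallest adjusted p was 0.952, and 359 had an unadjusted p under 0.05, 186 higher and 173 lower in captopril cortex. With the trend and robust options 1 named gene passed at its brightest probe, beside the dimmer Cdk5rap1 probe above. This was Cyp2c23, an arachidonic acid epoxygenase of the kidney, at 9.92 ± 0.13 in control and 9.25 ± 0.10 in captopril cortex (SD, n = 3). Its log2 difference of -0.67 (SE 0.13) had an adjusted p of 0.952 in the limma fit as designed and of 0.0378 with those options, and over all its alternatives from 0.0378 to 1.00. Over all probes, 707 of 16500 (4.28%) had an unadjusted p under 0.05, against 825 by chance, and 97.6% had an absolute log2 fold change under 0.5. In 848 genes, or 8.73%, the groups did not overlap, a share that chance puts at 10%.

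The genes with the smallest unadjusted p and higher values in captopril cortex, none past the threshold, had modest differences. Detected on all 6 arrays were Lcn2, which encodes the tubular injury marker lipocalin 2, at 5.98 ± 0.10 in control and 6.65 ± 0.24 in captopril cortex (log2 difference 0.68, SE 0.16). Also detected on all 6 arrays, Tacc1 differed by 0.61 (SE 0.13) and the kinase gene Stk35 by 0.65 (SE 0.15). The other Stk35 probe gave 0.24. Likewise detected on all 6 arrays, the retinoblastoma-like gene Rbl1 differed by 0.64 (SE 0.14) and Sh3bgrl by 0.80 (SE 0.17). These sizes depended on the processing, since without background correction and in the authors' values they were 0.27 and 0.15 for Lcn2, 0.31 and 0.18 for Tacc1, 0.26 and 0.14 for Stk35, 0.19 and 0.09 for Rbl1, and 0.23 and 0.12 for Sh3bgrl. Shtn1, Enoph1, Golim4 and Rpa2 were detected on all captopril arrays but on only 1 or 2 of the 3 control arrays, too near the detection limit for a fold. Rgs1, a regulator of G protein signalling, was detected on all 3 captopril arrays and on no control array, which makes it at least 1.29-fold higher. On the same basis Pcdh7 was at least 1.46-fold higher and Mlkl, the effector of necroptosis, at least 1.53-fold higher. These bounds hold on the neqc scale only, and log2 differences were smaller without background correction and in the authors' values. They were 0.35 and 0.16 for Rgs1, 0.17 and 0.08 for Pcdh7, and 0.21 and 0.10 for Mlkl. The adjusted p values of these genes lay between 0.952 and 0.989 in limma.

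On the lower side, also with none past the threshold in limma, Echdc3 differed by -0.50 (SE 0.12) and Washc1, a subunit of the WASH complex, by -0.58 (SE 0.13), or by -0.14 each in the authors' values. The probes of Faap24 disagreed, at -0.64 for its brighter probe (-0.13 in the authors' values) and 0.59 for the other. Wdr53 and Ncs1 were detected on all control arrays but on only 1 captopril array, too near the detection limit for a fold. A further 5 genes were detected on all control arrays and on no captopril array. On the neqc scale Alg11, a mannosyltransferase gene of N-glycan synthesis, was at least 1.53-fold lower, Dusp13 at least 1.28-fold, Extl1 at least 1.19-fold, Pcnx2 at least 1.12-fold and Cel at least 1.08-fold lower. These bounds do not hold for other processing. Log2 differences without background correction and in the authors' values were -0.19 and -0.09 for Alg11 and -0.19 and -0.09 for Dusp13. They were -0.15 and -0.07 for Extl1, -0.23 and -0.10 for Pcnx2, and -0.23 and -0.11 for Cel.

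In the renin-angiotensin system, 11 list members were tested and 0 passed the threshold in limma, over all probes or adjusted over the list alone; 1 had an unadjusted p under 0.05. That gene was Agt, which encodes angiotensinogen, at 7.53 ± 0.35 in control and 6.95 ± 0.23 in captopril cortex (SD, n = 3), a log2 difference of -0.57 (SE 0.20, 95% interval -1.04 to -0.10), which was -0.20 in the authors' values. Ace, which encodes the enzyme that captopril inhibits, differed by 0.12 (SE 0.18), and its 3 probes ranged from -0.29 to 0.12. The angiotensin receptor gene Agtr1a differed by -0.08 (SE 0.15) and the receptor gene Mas1 by 0.20 (SE 0.25), or 0.04 in the authors' values. Among the peptidases Anpep differed by 0.27 (SE 0.13), Mme by 0.09, Prcp by 0.08, Ctsa by 0.07, Prep by 0.01 and Thop1 by -0.08. The 4 probes of Ctsa disagreed, from -0.19 to 0.15, and the other Prep probe gave 0.35. Atp6ap2, the prorenin receptor gene, differed by 0.18 (SE 0.13). The direction of Ace and Ctsa turned when the probes of a gene were averaged, to -0.06 and -0.02. The list as a whole had a median of 0.08 and a camera adjusted p of 0.638.

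Among juxtaglomerular and macula densa genes, 7 were tested, 0 passed in limma and 1 had an unadjusted p under 0.05. Gja5, a connexin gene of renin cells, stood at 6.70 ± 0.34 in control and 6.10 ± 0.34 in captopril cortex (log2 difference -0.60, SE 0.23, or -0.14 in the authors' values). The other Gja5 probe gave -0.35. Rgs5 was detected on all control arrays and 2 captopril arrays, too near the detection limit for a fold. Abcc9 differed by 0.12 (0.03 in the authors' values) and Gucy1a1 by 0.10, and the probes of Gucy1a1 ranged from -0.05 to 0.46. The list had a camera adjusted p of 0.638. Probes of Ptgs2, Nos1, Agtr1b, Agtr2, Enpep, Cma1, Ptger4 and Foxd1 were too dim to be tested.

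The prostaglandin and eicosanoid list held members with lower and members with higher values. Of 9 tested genes, 0 passed over all probes in limma, and 2 passed adjusted over the list alone, Cyp2c23 (adjusted p = 0.00874) and Ptger3 (adjusted p = 0.0366). Adjustment over a list alone was made for each list by itself, without adjustment over the lists, so some such calls may arise by chance. Ptger3, which encodes a prostaglandin E2 receptor, was detected on all 3 control arrays and on 1 captopril array, too near the detection limit for a fold. Hpgd, whose product degrades prostaglandins, was detected on 1 control array and all captopril arrays. Ptger3 and Hpgd were named after their values were seen. The test of change in either direction, fry, gave this list alone an adjusted p under the threshold, 0.00184, and camera gave 0.795. That call was lost without captopril array 2 (adjusted p = 0.0983 in limma's fry) or captopril array 3 (0.0709), and with the replicate block (0.0616). It was also lost with the alternatives chosen after seeing the data, the brown fat covariate (0.142) and the fit without captopril arrays 1 and 3 (0.123).

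Interferon response genes were higher as a list in captopril cortex in camera at the preset correlation (median log2 difference 0.25, adjusted p = 0.00751), a call that was lost with an estimated correlation (adjusted p = 0.912). Of 15 tested members 12 had higher values and 0 passed the threshold singly. Examples were Igtp, an interferon-inducible GTPase gene, at 0.47 (SE 0.18), Usp18 at 0.33 (SE 0.13) and Oasl2 at 0.46 (SE 0.22). The other Oasl2 probe gave 0.19. Ifit2 gave 0.39 (SE 0.15) for its brighter probe and -0.19 for the other. Without background correction and in the authors' values the differences were 0.39 and 0.33 for Igtp, 0.16 and 0.10 for Usp18, 0.14 and 0.07 for Oasl2, and 0.18 and 0.10 for Ifit2. Macrophage and dendritic cell markers were also higher as a list at the preset correlation (median 0.21, camera adjusted p = 0.029), a call likewise lost with an estimated correlation (adjusted p = 0.912). The macrophage median was 0.11 without captopril array 2, 0.12 without captopril array 1 and 0.13 without control array 2, against 0.33 without control array 1 and 0.40 without captopril array 3. The interferon median was 0.37 without captopril array 3. Of 15 macrophage list members 14 had higher values, which included the lysozyme gene Lyz1 at 0.46 (SE 0.24), the complement gene C1qc at 0.47 (SE 0.30, or 0.23 in the authors' values) and the invariant chain gene Cd74 at 0.24 (SE 0.15). The fractalkine receptor gene Cx3cr1 was detected on only 2 arrays of each group, too near the detection limit for a fold. With 1 array left out these moved from 0.28 to 0.74 for Lyz1, 0.18 to 0.81 for C1qc and 0.17 to 0.35 for Cd74, and among interferon genes from 0.28 to 0.61 for Igtp, 0.27 to 0.50 for Ifit2, 0.25 to 0.40 for Usp18 and 0.22 to 0.66 for Oasl2. Adjusted over each list alone, 0 members passed, and 3 interferon genes and 0 macrophage genes had an unadjusted p under 0.05. The rotation test fry called 0 lists in 1 direction, with 0 at an unadjusted p under 0.05. In camera at the preset correlation, with all 6 arrays and the other processing or model choices fixed beforehand, the adjusted p ran from 0.00122 to 0.0229 for interferon and from 0.00152 to 0.0247 for macrophage genes. Captopril array 3 did not share the difference. Its list level, centred on the 6 arrays, was -0.23 for interferon and -0.30 for macrophage genes, the lowest of all 6 arrays, against 0.31 and 0.26 for captopril array 1 and 0.23 and 0.37 for captopril array 2. The interferon call was lost without control array 1 (adjusted p = 0.0543), control array 3 (0.0691), captopril array 1 (0.482) or captopril array 2 (0.195) in camera of limma. The macrophage call was lost without control array 2 (adjusted p = 0.0595), control array 3 (0.342), captopril array 1 (0.492) or captopril array 2 (0.507) in camera of limma.

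**Figure D2:**
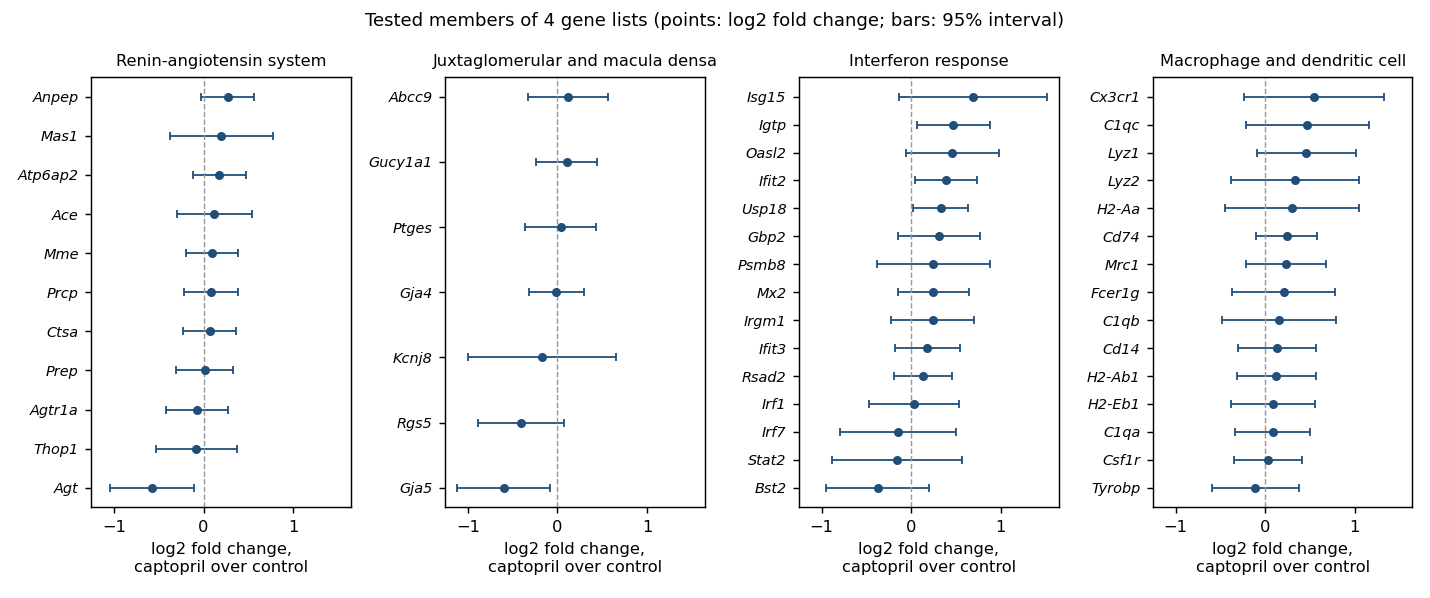
Log2 fold change of captopril over control with its 95% interval for each tested member of 4 lists (renin-angiotensin system, juxtaglomerular and macula densa, interferon response, macrophage and dendritic cell; n = 3 per group). Most interferon (12 of 15), macrophage (14 of 15) and renin-angiotensin (8 of 11) members lie to the right of 0. Agt is the lowest renin-angiotensin member at -0.57. Sizes of members near the detection limit, such as Cx3cr1 and Rgs5, are uncertain.

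Of clock genes, 12 were tested, and 0 passed over all probes or adjusted over the list alone in limma, with 0 at an unadjusted p under 0.05. Nr1d1 differed by -0.26 (SE 0.13), Per2 by 0.28 (SE 0.15), Dbp by -0.16 (SE 0.12) and Clock by 0.17 (SE 0.14), with Nr1d1 at -0.13 and Clock at 0.11 in the authors' values, and the list had a camera adjusted p of 0.885. Of 11 immediate early genes 0 passed in limma, and 2 had an unadjusted p under 0.05. Socs3, an inhibitor of cytokine signalling, differed by -0.67 (SE 0.18) and the transcription factor gene Klf4 by -0.57 (SE 0.18), or by -0.09 and -0.08 in the authors' values. Ier3 differed by 0.27 (SE 0.13) and Egr2 was detected on only 1 control and 2 captopril arrays, too near the detection limit for a fold, and the list's camera adjusted p was 0.928.

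No list of nephron segment or cell type markers in this paragraph passed camera's threshold. The proximal tubule list of 22 tested genes had a median of -0.04 (camera adjusted p = 0.928) and the loop of Henle and distal convoluted tubule list of 15 had a median of -0.002 (0.928). The collecting duct list had a median of -0.03 (0.928) and the list of medullary genes 0.07 (0.43). Podocyte genes had a median of -0.08 (camera adjusted p 0.232), endothelial genes 0.01 (0.849) and fibroblast and matrix genes 0.13 (0.638). Of the adrenal list 0 genes were tested. Adipocyte genes had a median of 0.21 (camera adjusted p = 0.143), and their level differed within groups, from -0.35 to 0.05 in controls and from -0.29 to 0.40 in captopril cortex. Captopril arrays 1 and 3 were the highest, at 0.40 and 0.30.

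**Figure D3:**
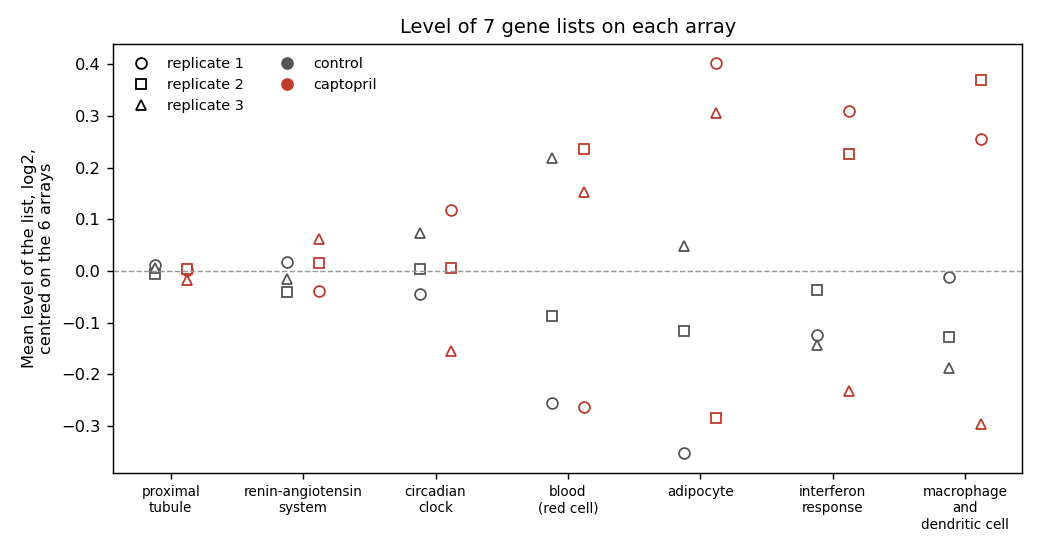
Mean level of 7 lists on each array (log2, each gene centred on the 6 arrays), with control in grey, captopril in red and symbols for the replicate number. Proximal tubule levels lie within 0.03 of each other, adipocyte levels span 0.75, and captopril array 3 is lowest for the interferon (-0.23) and macrophage (-0.30) lists.

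In total 2 of 32 tested lists passed camera's threshold, and the other 30 had adjusted p values between 0.143 and 0.928. The tubular injury list stood at 0.849, although Lcn2 passed adjusted over that list alone (adjusted p = 0.0266 in limma) and over the medullary list. In the neutrophil and platelet list, with 3 tested genes, Gp9 passed adjusted over the list alone (adjusted p = 0.0181 in limma). Gp9, named after its value was seen, was not detected on any control array. The calls of Lcn2 and Gp9 over a list alone likewise carry no adjustment over the lists. Oxidative phosphorylation (median 0.02), ribosomal proteins (-0.04), fatty acid oxidation (-0.04) and the unfolded protein response (-0.001) were likewise not called.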

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

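The alternatives without captopril arrays 1 and 3 and with a brown fat covariate were chosen after seeing the data; all others were fixed beforehand. The count of 3 lower probes stood at 5 with trend and robust options, at 0 with the replicate number as a block, at 0 without captopril arrays 1 and 3, where the lone captopril array is assumed to vary like the controls, and at 2 whichever single array was left out. The named genes counted 1 with trend and robust options (Cyp2c23, by its brightest probe) and 0 under every other alternative. The 2 lists became 4 without background correction, with adipocyte and inflammatory chemokine genes added, and 4 with normexp at offset 50. They were 3 with the stricter detection filter, with trend and robust options and with the brown fat covariate. They became 0 with an estimated correlation, 0 with fry, and between 0 and 3 with 1 array left out. The cause was not tested, except that leaving out arrays lowers the number of samples. Deviations of same-numbered arrays correlated at 0.004 to 0.04, against -0.06 to 0.04 for other numbers across groups, and 3 of 6 arrays correlated best with their own number. These values gave no clear sign of a pairing by replicate number but cannot exclude it. ILMN_2620114 and ILMN_2777226 kept their direction under all 17 alternatives, with log2 fold changes of -2.54 to -2.26 and -2.73 to -1.46, and passed under 15 each. The count was also 2 with median scaling, without a filter and with the brown fat covariate. ILMN_1238042 ranged from -1.83 to -0.51 and passed under 6. The 55 named genes kept their direction in 847 of 858 values. Averaging a gene's probes turned Ace to -0.0583 and Ctsa to -0.0180. With 1 array left out the ranges that crossed 0 were -0.0188 to 0.305 for Ace, -0.23 to 0.0611 for Thop1, -4.98e-05 to 0.13 for Ctsa, -0.0643 to 0.10 for Prep, -0.0648 to 0.37 for Mas1, -0.00762 to 0.33 for Abcc9 and -0.16 to 0.0478 for Agtr1a. A slide block was not run because the headers used here give no slide. Near the background, where the lowest detected value of an array reached up to 5.09 on the log2 scale, fold changes depend on the background correction and are bounds at best.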

Other observations

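Tests of background correction, of a variant under 1 probe, of correlated list members, of adipose tissue and of captopril as the only source were chosen after their results were seen, as was the spread set beside the test of a single array, and the chemokine, lymphocyte, corticosteroid-responsive, brown fat, Cish, Bcl6 and Erdr1 genes were named after their values were seen.

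In the list of inflammatory cytokines and chemokines 7 of 10 tested genes had higher and 3 lower values. Cxcl9 stood at 6.74 ± 0.19 in control and 7.57 ± 0.58 in captopril cortex (log2 difference 0.83, SE 0.27), Cxcl10 differed by 0.60 (SE 0.26) and Icam1, an endothelial adhesion gene, by 0.31 (SE 0.12), while Cxcl1 differed by -0.31 (SE 0.21) and Il18 by -0.12 (SE 0.18). In the authors' values these were 0.29 for Cxcl9, 0.18 for Cxcl10, 0.13 for Icam1, -0.06 for Cxcl1 and -0.02 for Il18. In limma 0 of them passed the threshold and 3 had an unadjusted p under 0.05, and the list had a camera adjusted p of 0.143. The 4 tested lymphocyte markers, Cd3d, Cd3g, Cd79b and Nkg7, had higher values but were not detected on all arrays, and are too few for a list test. Of 15 tested corticosteroid-responsive genes 9 had higher and 6 lower values. Sgk1, a kinase that promotes sodium reabsorption, differed by 0.28 (SE 0.12) and Fkbp5 by 0.45 (SE 0.22, or 0.27 in the authors' values), Hsd11b2 by -0.13 (SE 0.19) and Atp1b1 by -0.12 (SE 0.12), and that list had a camera adjusted p of 0.602. Nphs1, which encodes the slit diaphragm protein nephrin, differed by -0.48 (SE 0.19, or -0.10 in the authors' values), without passing, in a podocyte list with 2 higher and 7 lower values.

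The decrease at 3 unnamed probes and the lower values of the 3 Cdk5rap1 probes were set against technical explanations. Mice of different C57BL/6 substrains were predicted to differ by 1 or more in Nnt, Wdfy1, Entpd4 or Ide. No 95% interval of the brightest probe of these genes reached farther from 0 than 0.64 on the log2 scale, and the other Wdfy1 probe gave -0.33. The prediction assumes that the substrains differ in these genes and that the probes read the difference. Neither was checked, so a substrain difference stays open. Under 5 ways of background correction and normalization the highest upper bound was -0.40 for the unnamed probes and -0.22 for Cdk5rap1. All 3 Cdk5rap1 probes had intervals wholly below 0. The direction thus did not rest on 1 way of processing or on 1 Cdk5rap1 probe. Probes picked for low values on these arrays were likely to keep such intervals, so the intervals cannot set chance aside. The real grouping gave 3 probes and the highest other split 1. Of the 10 splits of the arrays into 3 and 3, 1, the real one, gave as many, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 in limma the real grouping had the fewest probes, 707, against 726 to 1353 in the other splits. The arrays therefore held no broad difference by treatment beyond that of other splits. A response to captopril may underlie the lower signals, as a hypothesis found and tested on the same data. It was not separated from differences between mice. The Cdk5rap1 probe ILMN_1249441 ran from 8.10 to 9.12 among controls alone. With the replicate block 0 of the 3 unnamed probes passed in limma.

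The higher interferon and macrophage lists may reflect mice that differed in immune activity rather than the drug, since members of a list varied together between arrays (estimated correlation 0.39 and 0.44), and allowing for that gave an adjusted p of 0.912. A single captopril array as source was predicted to take a list's median to 0 or below when left out. The lowest median without 1 array was 0.19 for interferon and 0.11 for macrophage genes. The SD over the 6 such medians, 0.07 and 0.12, comes from overlapping sets of arrays and decides nothing. Captopril arrays 1 and 2 stood at 0.31 and 0.23 for interferon genes (controls up to -0.04). For macrophage genes they stood at 0.26 and 0.37 (controls up to -0.01). This argues against 1 captopril array alone, although captopril array 3 was the lowest array in both lists. The real grouping gave 2 lists and the highest other split also 2. As many were given by 4 of the 10 splits, so the count of lists does not set the real grouping apart from other splits. The 3 other such splits called the same 2 lists, and captopril was not shown to be their source, since camera with an estimated correlation and fry (adjusted p = 0.880 for both lists in limma) called neither.

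Transcripts of brown fat, Cox8b, Cidea and Thrsp, were among the 6 genes with the widest range over arrays, at 4.15, 3.16 and 2.47 log2 units. Each range starts on control array 1, at 4.36, 4.54 and 4.99, below that array's lowest detected value of 5.02. The sizes of these ranges therefore depend on the background correction. A candidate explanation is adipose tissue in the dissected cortex. The mean of these genes followed the other adipocyte genes over the 6 arrays (Pearson r = 0.958, exact permutation p = 0.00694, Spearman rho = 0.943 with exact permutation p = 0.0167), with Benjamini-Hochberg p = 0.0417 by exact permutation over 6 relations and r = 0.901 without the 2 arrays farthest from the median. Single fat genes did not pass after adjustment, and Ucp1 gave Pearson r = 0.886 (exact permutation p = 0.0472, Benjamini-Hochberg p = 0.0944, r = 0.981 without the 2 farthest arrays) and Spearman rho = 0.714 (exact permutation p = 0.136). Adipoq gave Pearson r = 0.899 (exact permutation p = 0.0181, Benjamini-Hochberg p = 0.0542, r = 0.784 without the 2 farthest) and Spearman rho = 0.943 (exact permutation p = 0.0167). Captopril alone was not the source, because the untreated controls already differed, with the mean of these genes at 5.65 on control array 2 and 6.64 on control array 3. The range of 2.01 over the 3 controls starts at 4.63 on control array 1, below detection, and is uncertain in size. Captopril arrays 1 and 3 lay above all controls, so an added effect of the drug stays open.

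A hypothesis on growth hormone and STAT5 signalling was tested on Cish and Bcl6, whose levels ranged over 2.75 and 3.26 log2 units between arrays. They ran in opposite directions (Pearson r = -0.753, exact permutation p = 0.0722, Spearman rho = -0.886 with exact permutation p = 0.0333), with Benjamini-Hochberg p = 0.108 by exact permutation and r = -0.95 without the 2 farthest arrays. The pair was picked after these opposite directions were seen, so its p-values lend no support. If STAT5 activity differed between mice, its target Socs2 might follow Cish, and it did not reach that prediction (Pearson r = 0.0642, exact permutation p = 0.901, Spearman rho = 0.0286 with exact permutation p = 1, Benjamini-Hochberg p = 0.994, r = -0.227 without the 2 farthest arrays). For Igf1, another target, Pearson r was 0.00451 (exact permutation p = 0.994, Benjamini-Hochberg p = 0.994), Spearman rho 0.0857 (exact permutation p = 0.919), and r was 0.672 without the 2 farthest arrays. The hypothesis was not borne out and, with 6 arrays, not excluded. The 3 controls differed by 2.06 in Cish, so captopril alone was not the source.

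Erdr1 had the widest range of all genes, 5.78 log2 units, with values of 10.30, 9.69 and 8.59 on control array 2 and captopril arrays 1 and 2, and of 5.06, 4.52 and 4.88 on the other 3 arrays. On control array 3 and captopril array 3 it lay below the lowest detected value, 5.05 on each, so the size of that range depends on the background correction. The fry test in either direction gave 1 list in the real grouping and up to 6 in another split; 7 of the 10 splits gave as many. The split that joined control array 1 with captopril arrays 1 and 2 called 6 lists. It was the highest of the 10 splits, so its count alone cannot tell a structure of the samples apart from treatment from chance.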
